A study of Mus musculus with 9 samples.

How the data were processed

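Gene expression was measured on arrays of biotin-labelled amplified RNA from podocytes of 5 OVE26 diabetic and 4 normal FVB mice aged 3 to 4 months. Per the labels' protocols, kidneys were perfused with magnetic beads and digested with collagenase, glomeruli were collected on magnets and dissociated with trypsin, and fluorescent podocytes were sorted. RNA was isolated with a PicoPure kit and amplified and labelled with a NuGEN kit, per the labels. Per the submitters' processing notes the data were processed with RMA and Partek, and versions and settings are not given in the sources used here. The deposited values are probe set intensities on a linear scale, as judged from their range, and log2 was taken here before any test. The labels name the arrays as separate mice in each group, so p-values for single genes and scores rest on the spread between these arrays. That spread also holds any differences between sorts and amplifications, which cannot be told apart from differences between mice. P-values for lists from camera at its preset correlation compare a list's genes with other genes, taken as nearly independent. Those p-values do not measure the spread between mice. The labels give neither the sex of the mice nor batches or scan dates.

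The table holds 45101 probe sets on 9 arrays. Control probe sets (64) were left out. Gene symbols came from the platform annotation, which lists 1 symbol for 34945 probe sets, several for 932 and none for 9160. For 34741 of the first kind the gene identifier matched the reference gene table, and 0 symbols were updated. For each gene with more than 1 probe set (9010 genes) the brightest probe set over all 9 arrays was used, which left 18193 genes, with no filter on dim genes. Among the genes named in the text, some other probe sets ran against the one used for Sla, Rps18, Idh2, Top2a, Inhba, Slc12a1 and Lrp2.

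Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, all 9 arrays, 2-sided, prior degrees of freedom 2.94), with Benjamini-Hochberg adjustment over 18193 genes and a threshold of 0.05. Changes of at least 2-fold were counted among these. Lists of genes were tested with camera from limma at its preset correlation of 0.01, with adjustment over the 49 lists that had at least 5 measured genes, and 1230 of the 1370 genes on these lists were measured. Each list was also counted with Benjamini-Hochberg adjustment over its own genes ("adjusted over the list alone"). The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined.

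The lists covered cell types (podocyte, glomerular endothelial, mesangial, parietal epithelial, smooth muscle, proximal tubule, loop with distal tubule and collecting duct, macrophage, T and NK, B and plasma cell, neutrophil, and red blood cell with platelet markers), pathways of diabetic kidney disease, metabolism, inflammation, matrix and signalling, and technical sets (immediate early, heat shock, ribosomal, histone, sex-linked and pancreatic genes). The macrophage list shares 3 of its 28 genes with another list and the loop, distal tubule and collecting duct list shares 0. In FVB arrays 21 of the 28 genes of the latter and 10 of the 28 macrophage genes were above the 40th percentile of mean log2 intensity, so part of these genes had signal in the normal sorts too.

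Genes were named by 3 criteria. From genes past the threshold whose OVE26 arrays all lay on the same side of the FVB arrays and whose mean was at or above the 40th percentile (5.03 on the log2 scale), the 12 largest rises and 12 largest falls were taken, without symbols of unnamed clones. The result of 1 list is not reported here. For each list described, up to 4 members with the smallest p were taken. A set of 7 podocyte and sex genes was always named, of which 6 were measured and 1 is not analysed here. Genes outside these criteria are said to have been chosen after their values were seen.

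Cell type scores are the mean of a list's log2 values, each gene centred over the 9 arrays, and were compared between groups by 2-sided exact permutation over the 126 splits of 9 arrays into 5 and 4, adjusted over 33 measures. Scores of nephron segments, male-biased genes and clock genes were composed after the data had been seen.

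The alternatives fixed beforehand were a filter on dim genes, the mean of a gene's probe sets, all probe sets singly, quantile normalization, centring on array medians or on ribosomal protein genes, an intensity trend with robust variance, array weights, replicate number as a block, a sex covariate from Xist and the Y-linked genes, scores of proximal tubule, endothelial and mesangial markers as covariates, a linear model without moderation, leaving out each array, thresholds of 0.01 and 0.1, camera with estimated correlation, and fry. Those added after the data had been seen were leaving out OVE26 2 and OVE26 4 together, scores of the distal list or the macrophage list as covariates, the arrays of either Xist level alone, and the arrays numbered 1 to 4 without the block.

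The procedure was tested on simulated data with the same 18193 genes and 5 against 4 arrays, of which 200 genes were changed. It recovered 65% of genes changed 2-fold and 90% of genes changed 4-fold, 6.06% of the called genes (10 genes) were not changed, and 0 genes were called by limma when none was changed. The changed list, all of whose genes were shifted up by the same amount, was called and 0 other lists were. Each of these results rests on a single random draw. Genes were simulated independently of each other, so this cannot show how often camera calls unchanged lists whose genes vary together. The noise was alike in all arrays, so it cannot show how often limma calls unchanged genes where single arrays stand apart. In the data the estimated correlation was 0.468 for the loop, distal tubule and collecting duct list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.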

Results

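Podocytes, the epithelial cells that wrap the glomerular capillaries and form the filtration slits of the kidney, were compared between diabetic and normal mice. OVE26 mice are a transgenic model of early-onset type 1 diabetes on the FVB strain, and FVB mice served as the normal group. Podocytes carrying green fluorescent protein were collected by flow sorting from trypsin-digested glomeruli. RNA from each sort was amplified and read on 1 array, which gave 5 OVE26 and 4 FVB arrays from mice aged 3 to 4 months. All values are log2 intensities of probe sets, and differences are OVE26 minus FVB on the log2 scale. Median log2 intensity was 5.12 in both groups, with an SD of 0.03 in each. Across probe sets, which are not independent replicates, Pearson's r ranged from 0.960 to 0.985 between OVE26 arrays, from 0.980 to 0.989 between FVB arrays and from 0.964 to 0.984 between the groups. At most 4.08% of values were identical between any 2 arrays, so no array was a copy of another. The number of arrays limits the precision, and the median standard error of a difference was 0.16.

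The comparison asks which genes differ between podocytes of diabetic and normal mice. The sorts from OVE26 mice held more RNA of Lcn2, Clu, Pdk4, Rrm2 and the keratin Krt18, and less of Cacna2d2, Acsl6, Trib3 and Arhgap23. Lcn2, a secreted iron-carrier-binding protein made by injured kidney epithelium, rose from 3.18 ± 0.19 (SD, n = 4) in FVB to 7.63 ± 1.02 (SD, n = 5) in OVE26 arrays, a difference of 21.9-fold or more (limma, adjusted p = 0.00978). The FVB level lay below the 25th percentile of array values (3.32 on average) where signal is not told from background. Clu, which encodes the secreted chaperone clusterin, rose 8.75-fold from 8.67 ± 0.77 (SD, n = 4) to 11.80 ± 0.41 (SD, n = 5) (limma, adjusted p = 0.00978). Pdk4, the kinase that switches off pyruvate dehydrogenase, rose 9.90-fold from 5.77 ± 0.54 (SD, n = 4) to 9.08 ± 0.72 (SD, n = 5) (limma, adjusted p = 0.00978). Of 18193 genes tested, 86 were higher and 24 lower in OVE26 arrays at an adjusted p under 0.05. Of these, 67 rose and 11 fell at least 2-fold. In all 110 genes every OVE26 array lay on the same side of every FVB array, which held for 6.26% of all genes tested and is reached by chance in 1.59%.

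The other large rises were of several kinds. Slc7a12, an amino acid transporter, rose at least 21.3-fold (adjusted p = 0.0273), Rrm2, the small subunit of ribonucleotide reductase, at least 11.7-fold (adjusted p = 0.00978), and Aldh1a1, a retinaldehyde dehydrogenase, 9.28-fold (adjusted p = 0.0187). Atp6v0d2, a proton pump subunit of intercalated cells, rose 7.35-fold (adjusted p = 0.0290), Krt18, a keratin of simple epithelia, 6.75-fold (adjusted p = 0.0283), and Scg5, a chaperone of a prohormone convertase, 6.31-fold (adjusted p = 0.00978). Mt2, a metal-binding metallothionein, rose 6.14-fold (adjusted p = 0.0477), Plet1, an epithelial surface protein, 5.68-fold (adjusted p = 0.0254), and Fxyd4, a sodium pump regulator of the collecting duct, 5.28-fold (adjusted p = 0.00978). The folds of Slc7a12 and Rrm2 are lower bounds. Their FVB means of 2.61 and 3.27 lay below the 25th percentile too. Standard errors of these log2 differences ran from 0.28 for Fxyd4 to 0.68 for Slc7a12.

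The falls were smaller. Cacna2d2, an auxiliary calcium channel subunit, fell by 1.86 on the log2 scale (SE 0.28, adjusted p = 0.0254), from 9.97 ± 0.41 (SD, n = 4) in FVB to 8.11 ± 0.51 (SD, n = 5) in OVE26 arrays by limma. Acsl6, a long-chain acyl-CoA synthetase, fell by 1.77 (adjusted p = 0.0254), and Gja3, a connexin, fell by 1.47 (adjusted p = 0.0300). Sla, a Src-like adaptor, fell by 1.43 (adjusted p = 0.0436), with 3 of its 4 probe sets in that direction. Trib3, a pseudokinase induced by amino acid and endoplasmic reticulum stress, fell by 1.38 (adjusted p = 0.0290). Wt1os, annotated as the antisense partner of Wt1, fell by 1.26 (adjusted p = 0.0194), and whether its probe set separates the strands is not given in the sources used here. Arhgap23 fell by 1.08 (adjusted p = 0.00978), and Mtcl1, a microtubule crosslinker, fell by 0.99 (adjusted p = 0.0254). Tspyl5 fell by 0.95 (adjusted p = 0.0463), Tdrd5, a tudor-domain gene on the podocyte list, fell by 0.94 (adjusted p = 0.0462), Ajuba, a LIM protein of cell junctions and Hippo signalling, fell by 0.90 (adjusted p = 0.0244), and Endov, an inosine-specific endonuclease, fell by 0.88 (adjusted p = 0.0353).

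Without 1 array the count of higher genes was 64 (OVE26 1), 107 (OVE26 2), 20 (OVE26 3), 44 (OVE26 4), 27 (OVE26 5), 21 (FVB 1), 285 (FVB 2), 8 (FVB 3) and 26 (FVB 4). That of lower genes was 21 (OVE26 1), 28 (OVE26 2), 3 (OVE26 3), 17 (OVE26 4), 3 (OVE26 5), 2 (FVB 1), 82 (FVB 2), 0 (FVB 3, by limma, with 2155 genes at an unadjusted p under 0.05) and 2 (FVB 4). Lcn2, Pdk4, Clu and Fxyd4 passed in all 9 such fits, whereas the other 20 of the 24 genes with the largest changes missed the threshold in at least 1. Rrm2, Scg5 and Arhgap23 missed it without FVB 3 alone and Aldh1a1 in 3 fits. The rest missed it in 5 or more, up to 7 for Sla, Trib3, Tspyl5 and Endov and 8 for Mt2 and Tdrd5. With the sex covariate 11 of the 24 genes passed and all 24 kept their direction.

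**Figure D1:**
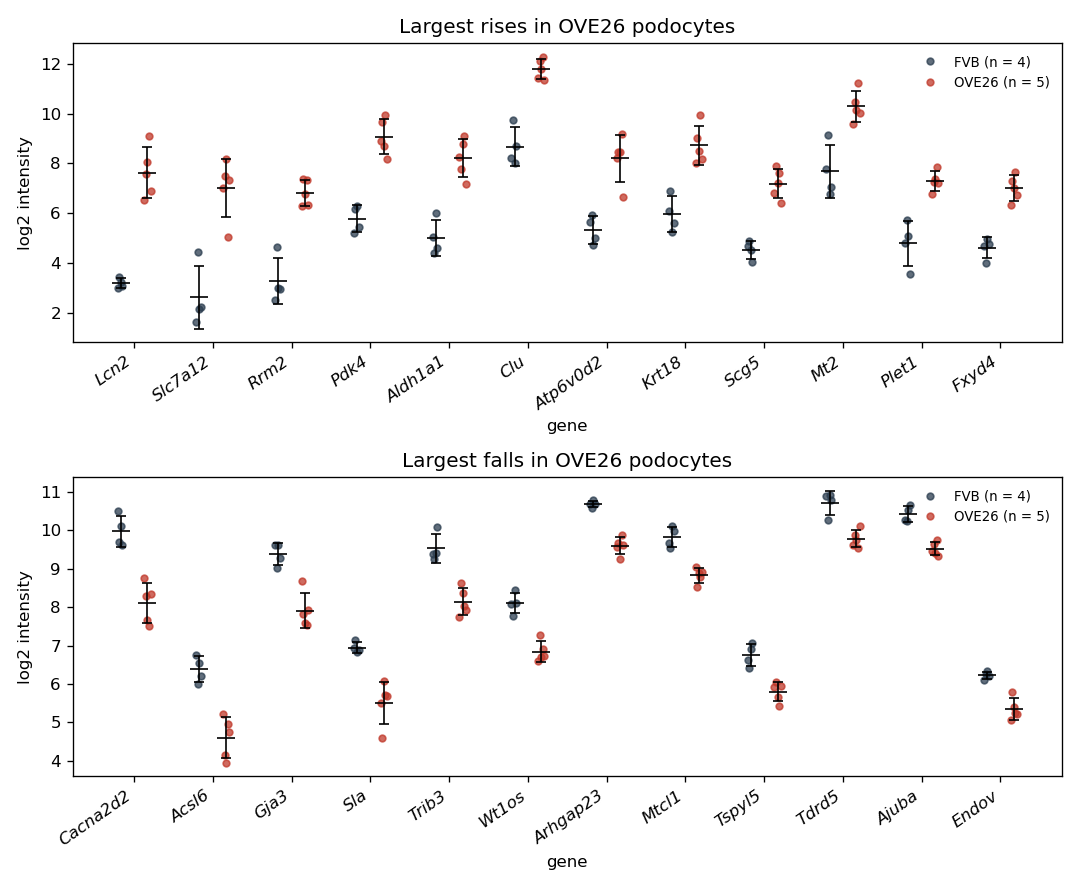
Log2 intensity (vertical axis) of the 12 largest rises and 12 largest falls (horizontal axis) in FVB (n = 4, dark blue) and OVE26 (n = 5, red) arrays, where points are arrays, dashes are means and bars are SD. Lcn2 lay at 3.18 in FVB and 7.63 in OVE26 arrays on average, and Cacna2d2 at 9.97 and 8.11.

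The list of podocyte markers was called lower by camera, with a small median. Of 37 podocyte genes measured, 1 fell (Tdrd5) and 36 did not pass by limma, and adjusted over the list alone 6 were lower. Tdrd5 missed the threshold in 8 of the 9 fits with 1 array left out. The list's median difference was -0.21 (camera, adjusted p = 7.03e-08; adjusted p = 0.313 with an estimated correlation). With the macrophage score as a covariate, added after the data had been seen, the call ended. The median was then -0.02 (adjusted p = 0.143). Foxc2, a podocyte transcription factor, differed by -0.78 (adjusted p = 0.0828), Lmx1b, mutated in nail-patella syndrome, by -0.65 (adjusted p = 0.118), and Kirrel, a slit diaphragm protein, by -0.56 (adjusted p = 0.139). Nphs1, which encodes the slit diaphragm protein nephrin, was at 11.40 ± 0.29 (SD, n = 5) against 11.90 ± 0.23 (SD, n = 4) (limma, adjusted p = 0.205), and Wt1, a podocyte transcription factor, differed by -0.39 (adjusted p = 0.208). The sialomucin gene Podxl differed by -0.11 (adjusted p = 0.574), the actin-binding synaptopodin gene Synpo by -0.15 (adjusted p = 0.497), and Vegfa, the endothelial growth factor made by podocytes, by -0.21 (adjusted p = 0.351). Podxl and Synpo were bright in both groups, at 12.99 and 12.89 in OVE26 and 13.10 and 13.03 in FVB arrays.

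Some genes of the collecting duct and 3 keratin genes were higher in the OVE26 sorts. Of 28 markers of the loop, distal tubule and collecting duct, 3 rose and 25 did not pass by limma, and adjusted over the list alone 15 were higher. Their median difference was 1.00 (camera, adjusted p = 7.73e-12; adjusted p = 0.252 with an estimated correlation). The members that rose were Fxyd4, Atp6v0d2 and Slc26a4, the pendrin anion exchanger of intercalated cells, which rose by 2.14 (adjusted p = 0.0349). Slc26a4 passed in 2 of the 9 fits with 1 array left out and Atp6v0d2 in 3. Hsd11b2, which protects the mineralocorticoid receptor of principal cells from glucocorticoid, differed by 2.27 (adjusted p = 0.0516), and passed without OVE26 2 (1.94, adjusted p = 0.0411) or FVB 2 (2.37, adjusted p = 0.0465). Of 13 parietal epithelial markers 3 rose and 10 did not pass by limma, with 4 higher and 1 lower adjusted over the list alone. The median was 0.47 (camera, adjusted p = 0.000141; adjusted p = 0.138 with an estimated correlation; adjusted p = 0.143 with the macrophage covariate). The 3 were keratin genes, namely Krt8, up by 2.32 (adjusted p = 0.00978), Krt18, and Krt19, up by 1.30 (adjusted p = 0.0367), while the stem cell marker Prom1 differed by 1.83 (adjusted p = 0.120), or 2.41 without FVB 2 (adjusted p = 0.00530). Keratins are also made by tubule and collecting duct epithelium. Krt8 passed in 8 of the 9 fits with 1 array left out, Krt18 in 4 and Krt19 in 3.

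The epithelial-mesenchymal transition list of 19 genes holds keratins of that list too. In it 3 genes rose (Krt8, Krt18 and Mmp2, a matrix metalloproteinase, up by 1.18, adjusted p = 0.0244) and 16 did not pass by limma, with 6 higher and 1 lower adjusted over the list alone. Its median was 0.10 (camera, adjusted p = 0.0495; adjusted p = 0.322 with an estimated correlation). Krt8 and Krt18 mark epithelial rather than mesenchymal cells, and Foxc2, also listed, differed by -0.78. Mmp2 passed in 5 of the 9 fits with 1 array left out. The call ended without OVE26 2 (median 0.08, adjusted p = 0.108), OVE26 3 (0.05, adjusted p = 0.159), FVB 3 (0.06, adjusted p = 0.0883) or FVB 4 (0.08, adjusted p = 0.0741), and the median moved to 0.21 without OVE26 1, 0.17 without OVE26 4 and 0.17 without FVB 2. It also ended with the sex covariate (Xist minus the Y-linked mean; 0.03, adjusted p = 0.187), and with the score of the loop, distal tubule and collecting duct list (-0.11, adjusted p = 0.617) or of the macrophage list (0.28, adjusted p = 0.384) as a covariate. Other settings that ended it were the proximal covariate (0.11, adjusted p = 0.0685), the mean of a gene's probe sets (0.08, adjusted p = 0.143), quantile normalization (0.10, adjusted p = 0.0552) and the replicate block (0.11, adjusted p = 0.0566). So did leaving out OVE26 2 and OVE26 4 together (0.09, adjusted p = 0.0727) and taking only the arrays with Xist below the Y-linked genes (-0.01, adjusted p = 0.379).

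Scores of cell type markers, each the mean centred log2 intensity of a list, placed these changes beside the makeup of the sorts. The loop, distal tubule and collecting duct score was 0.52 ± 0.52 (SD, n = 5) in OVE26 and -0.65 ± 0.52 (SD, n = 4) in FVB arrays (2-sided exact permutation p = 0.00794, the smallest that 126 splits can give; adjusted p = 0.0374 over 33 measures). The macrophage score differed by 0.65 (exact permutation p = 0.0317, adjusted p = 0.131), the podocyte score differed by -0.25 (exact permutation p = 0.0476, adjusted p = 0.157) and the parietal score by 0.85 (exact permutation p = 0.00794, adjusted p = 0.0374). The proximal tubule score differed by -0.13 (exact permutation p = 0.937), or by 0.27 without OVE26 2 (exact permutation p = 0.200), the glomerular endothelial score by -0.08 (exact permutation p = 0.730) and the mesangial score by -0.16 (exact permutation p = 0.516). With the distal score as a covariate limma called 0 genes (1668 at an unadjusted p under 0.05), and with the macrophage score 1 gene, lower (2800 at an unadjusted p under 0.05), because standard errors of the 107 and 110 of these genes tested there grew to 1.62 and 1.61 times their size while their differences kept a median of 0.848 and 0.961 of theirs. These covariates were added after the data had been seen.

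**Figure D2:**
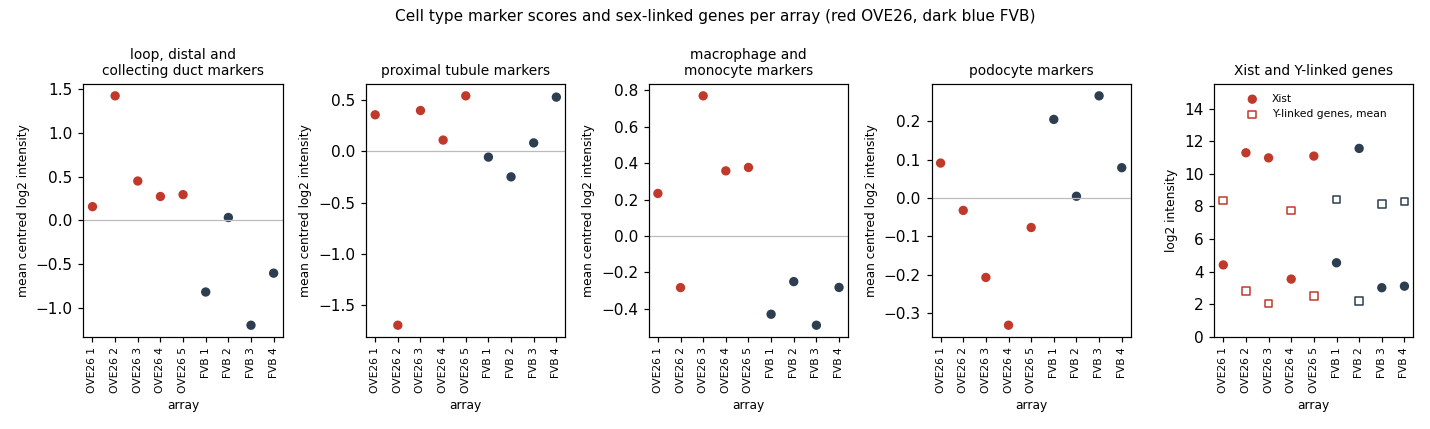
Mean centred log2 intensity of 4 marker lists, and log2 intensity of Xist (filled circles) and the mean of 3 Y-linked genes (open squares), on the vertical axes for each array on the horizontal axis (OVE26 red, FVB dark blue). The loop, distal tubule and collecting duct score ranged from 0.16 to 1.43 in OVE26 and from -1.20 to 0.03 in FVB arrays, and the proximal score of OVE26 2 was -1.69.

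Lists of energy metabolism were called higher by camera with small medians, and few of their members passed singly. Of 71 oxidative phosphorylation genes 1 rose and 70 did not pass by limma, with 9 higher adjusted over the list alone. The median was 0.20 (camera, adjusted p = 1.07e-11; adjusted p = 0.252 with an estimated correlation). The member that rose was Uqcr10, a complex III subunit (0.80, adjusted p = 0.0450), and Uqcr11, of the same complex, differed by 0.55 (adjusted p = 0.0828). Of 35 fatty acid oxidation genes and PPAR targets 2 rose and 33 did not pass by limma, with 11 higher adjusted over the list alone. The median was 0.29 (camera, adjusted p = 5.30e-08; adjusted p = 0.128 with an estimated correlation). Those 2 were Pdk4 and Angptl4, an inhibitor of lipoprotein lipase (0.86, adjusted p = 0.0403), while Acaa2, the mitochondrial thiolase, differed by 0.87 (adjusted p = 0.0570; 1.02 without FVB 2, adjusted p = 0.0154) and Cpt1a, which admits long-chain fatty acids to mitochondria, by 0.50 (adjusted p = 0.0690). Of 20 glycolysis genes 1 rose and 19 did not pass by limma, with 9 higher adjusted over the list alone. The median was 0.31 (camera, adjusted p = 3.60e-06; adjusted p = 0.165 with an estimated correlation). That gene was Pfkp, a phosphofructokinase (0.87, adjusted p = 0.0254), and lactate dehydrogenase A, Ldha, differed by 0.56 (adjusted p = 0.0516). When 1 array was left out, Uqcr10 and Angptl4 passed in 2 of 9 fits and Pfkp in 4. Uqcr10, Angptl4 and Pfkp also missed the threshold with the sex covariate (limma, adjusted p from 0.0583 to 0.0871).

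In the list of 23 genes of the TCA cycle and pyruvate dehydrogenase, 1 rose (Pdk4, which opposes entry of pyruvate into the cycle) and 22 did not pass by limma, with 1 higher adjusted over the list alone. Its median was 0.15 (camera, adjusted p = 0.000274; adjusted p = 0.128 with an estimated correlation), and Idh2 and Suclg2, enzymes of the cycle, differed by 0.44 (adjusted p = 0.161) and 0.41 (adjusted p = 0.160). Of 21 hypoxia response genes 1 rose and 20 did not pass by limma, with 2 higher adjusted over the list alone. The median was 0.29 (camera, adjusted p = 0.0363; adjusted p = 0.252 with an estimated correlation). Egln3, the HIF-induced prolyl hydroxylase, rose by 1.52 (adjusted p = 0.0144), and the mitophagy receptor Bnip3 differed by 0.53 (adjusted p = 0.239). The hypoxia call ended without OVE26 3 (median 0.22, adjusted p = 0.130) or FVB 4 (0.24, adjusted p = 0.0765). It also ended with the sex covariate (0.23, adjusted p = 0.0504), the distal covariate (0.20, adjusted p = 0.0530) and the macrophage covariate (0.18, adjusted p = 0.768). Other settings that ended it were the filter on dim genes (0.16, adjusted p = 0.0776) and the replicate block (0.26, adjusted p = 0.0510). So did taking only the arrays with Xist below the Y-linked genes (0.20, adjusted p = 0.101). Beside the metabolic lists, the loop, distal tubule and collecting duct score, which spans several nephron segments, was higher by 1.17 in OVE26 arrays. The proximal score differed by -0.13, or by 0.27 without OVE26 2. With the loop, distal tubule and collecting duct score as a covariate the oxidative phosphorylation and glycolysis calls ended, at medians of 0.07 (adjusted p = 0.115) and 0.12 (adjusted p = 0.111). With the macrophage score as a covariate the fatty acid oxidation and TCA cycle calls ended, at medians of 0.20 (adjusted p = 0.143) and 0.18 (adjusted p = 0.185).

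Lists of stress and hormone response were called higher by camera, and some of their members passed singly. Of 33 antioxidant and NRF2 target genes 1 rose (Mt2) and 32 did not pass by limma, with 12 higher adjusted over the list alone. Their median was 0.26 (camera, adjusted p = 5.04e-06; adjusted p = 0.252 with an estimated correlation), and the metallothionein Mt1 differed by 2.31 (adjusted p = 0.0573), the glutathione transferase Gsta3 by 1.55 (adjusted p = 0.0532) and sulfiredoxin, Srxn1, by 0.60 (adjusted p = 0.0723). Mt1 passed without FVB 2 (2.79, adjusted p = 0.00625), and Gsta3 without FVB 2 (1.81, adjusted p = 0.0154) or OVE26 2 (1.74, adjusted p = 0.0345). Mt2 missed the threshold in 8 of the 9 fits with 1 array left out. Of 16 glucocorticoid and steroid targets 4 rose and 12 did not pass by limma, with 5 higher adjusted over the list alone. The median was 0.65 (camera, adjusted p = 6.76e-05; adjusted p = 0.288 with an estimated correlation). The 4 were Lcn2, Pdk4, Angptl4 and Mt2, which also respond to inflammation, fasting or metals. Of 34 autophagy and lysosome genes 0 rose, 0 fell and 34 did not pass by limma (at an unadjusted p under 0.05, 10 were higher and 2 lower), with 1 higher adjusted over the list alone. The median was 0.15 (camera, adjusted p = 0.0114; adjusted p = 0.252 with an estimated correlation). The lysosomal protease gene Ctsd differed by 0.81 (adjusted p = 0.0570) and the proton pump subunit Atp6v1a by 0.46 (adjusted p = 0.120). Of 13 genes for NADPH oxidases and other oxidant sources 0 rose, 0 fell and 13 did not pass by limma (at an unadjusted p under 0.05, 4 were higher), with 0 higher and 0 lower adjusted over the list alone. Their median was 0.21 (camera, adjusted p = 0.0307; adjusted p = 0.290 with an estimated correlation), with Nox4, the main renal isoform, at 1.33 (adjusted p = 0.208) and Cybb, the phagocyte isoform, at 1.34 (adjusted p = 0.198). That call ended without OVE26 3 (median 0.11, adjusted p = 0.114), OVE26 4 (0.22, adjusted p = 0.0531), OVE26 5 (0.27, adjusted p = 0.0780) or FVB 3 (0.29, adjusted p = 0.0542), and the median moved to 0.32 without OVE26 1. It also ended with the sex covariate (0.16, adjusted p = 0.0876), the distal covariate (0.22, adjusted p = 0.207) and with the replicate block (0.27, adjusted p = 0.0510). The macrophage score, beside these lists, differed by 0.65 (adjusted p = 0.131). With it as a covariate the antioxidant (0.08, adjusted p = 0.768), steroid (0.16, adjusted p = 0.366) and autophagy calls (0.18, adjusted p = 0.310) ended.

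Immune gene lists were called higher by camera, although few of their members passed singly. Of 28 macrophage and monocyte markers 0 rose, 0 fell and 28 did not pass by limma (at an unadjusted p under 0.05, 12 were higher and 1 lower), with 11 higher and 1 lower adjusted over the list alone. The median was 0.52 (camera, adjusted p = 1.86e-05; adjusted p = 0.227 with an estimated correlation). Cd74, the invariant chain of antigen presentation, differed by 1.28 (adjusted p = 0.0516), cathepsin S, Ctss, by 2.61 (adjusted p = 0.0711), the signalling adaptor Tyrobp by 1.42 (adjusted p = 0.0805) and the complement gene C1qb by 2.30 (adjusted p = 0.0828). Without OVE26 2, Cd74 (1.49, adjusted p = 0.0142), Ctss (2.98, adjusted p = 0.0351) and C1qb (2.82, adjusted p = 0.00127) passed, and without FVB 2, Cd74 (1.36, adjusted p = 0.0401), Ctss (2.91, adjusted p = 0.0419) and Tyrobp (1.65, adjusted p = 0.0317) did. Of 38 interferon response genes 0 rose, 0 fell and 38 did not pass by limma (at an unadjusted p under 0.05, 7 were higher), with 2 higher adjusted over the list alone. The median was 0.56 (camera, adjusted p = 3.70e-06; adjusted p = 0.452 with an estimated correlation), or 0.25 without OVE26 3. The chemokine gene Cxcl10 differed by 2.35 (adjusted p = 0.0905) and the transcription factor gene Irf1 by 1.40 (adjusted p = 0.104). Of 15 complement genes 1 rose (Clu, which restrains the terminal complex) and 14 did not pass by limma, with 5 higher adjusted over the list alone. The median was 0.58 (camera, adjusted p = 6.76e-05; adjusted p = 0.252 with an estimated correlation), or 0.39 without OVE26 3.

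Of 30 genes for inflammatory cytokines, chemokines and NF-kappaB targets 0 rose, 0 fell and 30 did not pass by limma (at an unadjusted p under 0.05, 11 were higher and 2 lower), with 8 higher and 1 lower adjusted over the list alone. The median was 0.37 (camera, adjusted p = 0.000141; adjusted p = 0.252 with an estimated correlation). The neutrophil chemokine gene Cxcl1 differed by 1.77 (adjusted p = 0.0573; 1.96 without OVE26 2, adjusted p = 0.0471), Cxcl16 by 0.83 (adjusted p = 0.0659) and the inducible cyclooxygenase gene Ptgs2 by 2.17 (adjusted p = 0.0784). Of 33 immediate early genes, which digestion and sorting can induce, 0 rose, 0 fell and 33 did not pass by limma (at an unadjusted p under 0.05, 13 were higher and 4 lower), with 1 higher adjusted over the list alone. Their median was 0.47 (camera, adjusted p = 0.00199; adjusted p = 0.532 with an estimated correlation), with Egr2 at 3.16 (adjusted p = 0.0542), Myc at 1.63 (adjusted p = 0.117) and Fosl2 at -0.49 (adjusted p = 0.149). That call ended without OVE26 4 (median 0.23, adjusted p = 0.0581). With the macrophage score as a covariate, added after the data had been seen, the camera direction of the interferon, complement, inflammatory, immediate early and NADPH oxidase lists turned and none of these calls held, at adjusted p values from 0.451 to 0.899.

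The cell cycle list was called higher by camera, and 3 of its genes passed singly. Of 41 cell cycle genes 3 rose and 38 did not pass by limma, with 5 higher and 1 lower adjusted over the list alone. The median was 0.20 (camera, adjusted p = 0.00201; adjusted p = 0.165 with an estimated correlation). The 3 were Rrm2, the proliferation marker Mki67, up by 1.73 (adjusted p = 0.0254), and Gmnn, an inhibitor of replication licensing, up by 1.01 (adjusted p = 0.0244), while the topoisomerase gene Top2a differed by 1.11 (adjusted p = 0.0549; 0.92 without OVE26 5, adjusted p = 0.0383). Rrm2 passed in 8 of the 9 fits with 1 array left out, Gmnn in 5 and Mki67 in 3. The cell cycle call ended with the distal covariate (median 0.11, adjusted p = 0.271) and the macrophage covariate (0.22, adjusted p = 0.143), whose scores differed by 1.17 (adjusted p = 0.0374) and 0.65 (adjusted p = 0.131). Of 45 extracellular matrix and basement membrane genes 1 rose (Mmp2) and 44 did not pass by limma, with 4 higher and 1 lower adjusted over the list alone. Their median was 0.24 (camera, adjusted p = 0.00986; adjusted p = 0.295 with an estimated correlation), with fibronectin, Fn1, at 1.00 (adjusted p = 0.108), Col1a1, of fibrillar collagen, at 0.69 (adjusted p = 0.120) and the glomerular basement membrane laminin gene Lama5 at -0.53 (adjusted p = 0.108). That call ended with the same covariates (0.06, adjusted p = 0.298, and 0.06, adjusted p = 0.915). It also ended in the arrays with Xist below the Y-linked genes (2 OVE26 and 3 FVB; 0.16, adjusted p = 0.136). Of 42 ribosomal protein genes 0 rose, 0 fell and 42 did not pass by limma (at an unadjusted p under 0.05, 8 were higher), with 0 higher and 0 lower adjusted over the list alone. The median was 0.17 (camera, adjusted p = 6.76e-05; adjusted p = 0.452 with an estimated correlation), or 0.07 with arrays centred on their medians; Rps18 was at 0.24 (adjusted p = 0.248) and Rpl27a at 0.31 (adjusted p = 0.252). The ribosomal call ended with the macrophage covariate (0.15, adjusted p = 0.372).

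Mesangial markers were lower as a set by camera. Of 18 markers 0 rose, 0 fell and 18 did not pass by limma (at an unadjusted p under 0.05, 1 were higher and 2 lower), with 0 higher and 0 lower adjusted over the list alone. The median was -0.25 (camera, adjusted p = 0.0363; adjusted p = 0.576 with an estimated correlation). The pericyte gene Rgs5 was at 1.60 (adjusted p = 0.223), the secreted Wnt modulator Sfrp2 at -0.55 (adjusted p = 0.230) and the growth factor gene Ptn at -0.66 (adjusted p = 0.230). The call ended without OVE26 1 (median -0.18, adjusted p = 0.143), OVE26 2 (-0.18, adjusted p = 0.182), OVE26 5 (-0.22, adjusted p = 0.0994), FVB 2 (-0.10, adjusted p = 0.333) or FVB 4 (-0.23, adjusted p = 0.0706), and the median moved to -0.41 without OVE26 3 and -0.39 without FVB 3. It also ended with the filter on dim genes (-0.25, adjusted p = 0.0890), the mean of a gene's probe sets (-0.26, adjusted p = 0.151), and with arrays centred on their medians (-0.35, adjusted p = 0.0751) or on ribosomal protein genes (-0.39, adjusted p = 0.118). Array weights (-0.21, adjusted p = 0.0797), the replicate block (-0.22, adjusted p = 0.105) and the proximal covariate (-0.22, adjusted p = 0.0654) ended it too. So did leaving out OVE26 2 and OVE26 4 together (-0.13, adjusted p = 0.257).

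Of 49 lists tested, camera called 20 higher and 2 lower. With an estimated correlation 0 of these 22 calls held (8 had an unadjusted p under 0.05, and the smallest adjusted p was 0.128), while fry, which tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes, called 15 lists. Of the 22 lists fry called 14 and not the other 8: podocyte (adjusted p = 0.0772), interferon (0.211), steroid (0.0567), ribosomal (0.0772), immediate early (0.280), matrix (0.0622), NADPH oxidase (0.0683) and mesangial (0.499). The median difference of all genes was 0.01, and centring the arrays on ribosomal protein genes shifted it by -0.15. The share of called genes that were higher was 78.2%, against 56.3% with arrays centred on their medians (67 higher, 52 lower) and 53.9% with centring on ribosomal protein genes (55 higher, 47 lower).

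**Figure D3:**
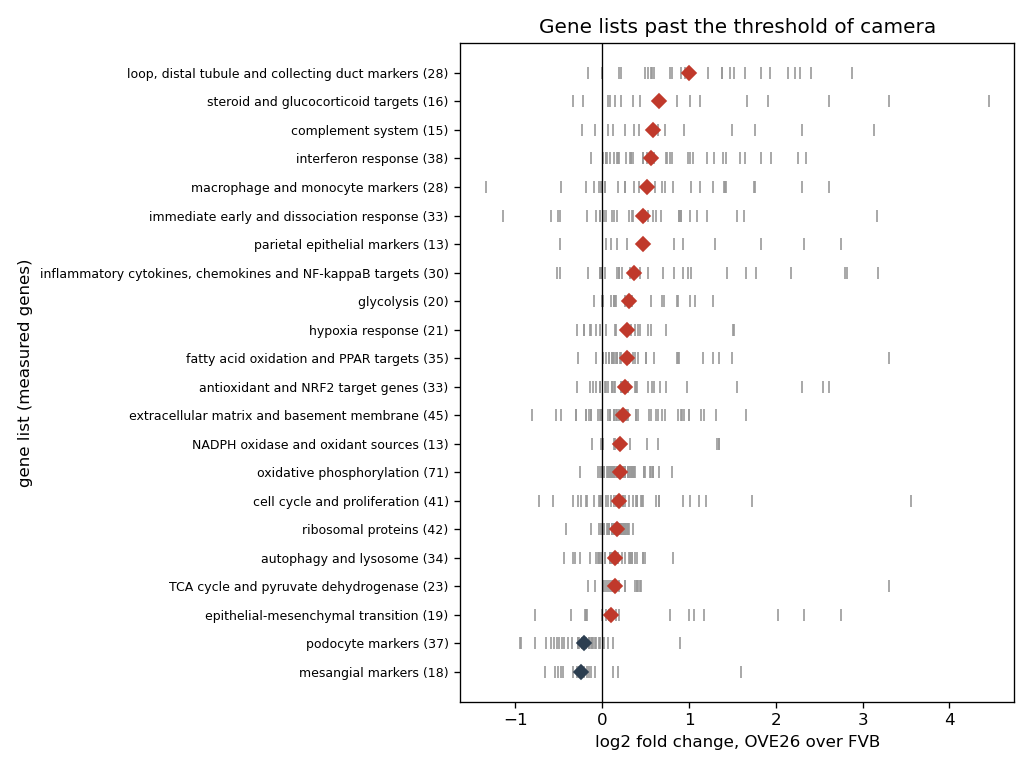
Log2 fold change of OVE26 over FVB (horizontal axis) for the measured genes (grey ticks) of the 22 gene lists called by camera (vertical axis, number of measured genes in brackets), where diamonds are list medians (red higher, dark blue lower). The medians ran from -0.25 for mesangial markers to 1.00 for loop, distal tubule and collecting duct markers.

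The other 27 lists were not called, and the medians of all but 1 are given as values. Among cell types, the median was -0.19 for glomerular endothelial markers (camera, adjusted p = 0.268), -0.08 for proximal tubule markers (adjusted p = 0.971), 0.05 for smooth muscle and pericyte markers (adjusted p = 0.651), -0.05 for T and NK cell markers (adjusted p = 0.309), 0.03 for B and plasma cell markers (adjusted p = 0.422), -0.03 for neutrophil markers (adjusted p = 0.760) and 0.02 for red blood cell and platelet genes (adjusted p = 0.949). Among stress and death pathways it was 0.13 for heat shock proteins (adjusted p = 0.0623), 0.14 for apoptosis (adjusted p = 0.183), 0.07 for p53 targets and senescence (adjusted p = 0.214), 0.12 for the unfolded protein response (adjusted p = 0.651) and 0.06 for the proteasome (adjusted p = 0.143). Among metabolic pathways it was 0.21 for glucose transport, polyol and hexosamine pathways (adjusted p = 0.105), 0.12 for cholesterol and fatty acid synthesis (adjusted p = 0.116), -0.05 for insulin and IGF signalling (adjusted p = 0.209) and 0.23 for the circadian clock (adjusted p = 0.258). Among signalling and structural lists it was 0.04 for TGF-beta (adjusted p = 0.407), -0.11 for YAP and TEAD targets (adjusted p = 0.209), -0.01 for Notch (adjusted p = 0.335), 0.02 for Wnt (adjusted p = 0.657), -0.04 for the renin-angiotensin system (adjusted p = 0.752), -0.01 for angiogenic factors (adjusted p = 0.479) and -0.10 for adhesion and integrins (adjusted p = 0.209). Without OVE26 2 the proximal tubule (median 0.39, adjusted p = 0.000865), heat shock (0.13, adjusted p = 0.0325), glucose transport (0.31, adjusted p = 0.0123), cholesterol (0.14, adjusted p = 0.0336) and proteasome lists (0.11, adjusted p = 0.0376) were called higher. Other calls gained by leaving out 1 array were heat shock without OVE26 1 (0.16, adjusted p = 0.0132), glucose transport without FVB 2 (0.18, adjusted p = 0.0491) and proteasome without FVB 4 (0.11, adjusted p = 0.0320). Glomerular endothelial markers were called lower without OVE26 3 (-0.26, adjusted p = 0.0223) or FVB 3 (-0.30, adjusted p = 0.00753). Endothelial markers were also called lower with the sex covariate (-0.34, adjusted p = 0.000414), the distal covariate (-0.52, adjusted p = 0.000121) and the macrophage covariate (-0.48, adjusted p = 5.21e-05), and in the arrays with Xist below the Y-linked genes (-0.30, adjusted p = 0.0400). Proximal tubule markers were called higher with the distal covariate (0.97, adjusted p = 1.34e-06) and lower with the macrophage covariate (-1.51, adjusted p = 9.02e-11). In other planned settings heat shock was called higher in 4 (adjusted p from 0.0226 to 0.0389), glucose transport in 4 (0.0342 to 0.0497), cholesterol with array weights (0.0308), the proteasome with the sex covariate (0.0335) and the clock with centring on ribosomal protein genes (0.0377). Fry called the adhesion and integrin list, lower (0.0253). Sex-linked genes had a median of -0.19 (adjusted p = 0.349), histone genes 0.01 (adjusted p = 0.948) and pancreatic genes 0.01 (adjusted p = 0.535).

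Of the members of those lists 5 rose and 2 fell singly, and the median, mean and camera direction were not of the same sign in several. Trib3 and Ajuba fell, and Lcn2 and Angptl4 were among the rises. Inhba, the activin A subunit, rose by 2.07 (adjusted p = 0.0254), Perp, a p53-induced membrane protein, by 1.44 (adjusted p = 0.00997) and Dapk2, a calmodulin-dependent death kinase, by 0.79 (adjusted p = 0.0273). Inhba, Perp and Dapk2 were chosen after their values were seen. Inhba passed in 2 of the 9 fits with 1 array left out, Dapk2 in 3 and Perp in 8. The mean was 0.09 for adhesion and integrins, 0.42 for neutrophil markers (to which Lcn2 belongs), 0.19 for angiogenic factors and -0.01 for the unfolded protein response, each opposite to the median. The camera direction was down for the Wnt list and the red blood cell and platelet list, whose medians and means were above 0, and for the histone list, whose mean was -0.01.

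The labels do not give the sex of the mice. Xist, which is expressed from the inactive X chromosome of females, was at 11.30, 10.99 and 11.09 in OVE26 2, 3 and 5 and at 11.57 in FVB 2, and between 3.01 and 4.54 in the other 5 arrays, where the mean of 3 Y-linked genes was 7.75 to 8.43 against 2.04 to 2.82. Its group difference was 2.71 (limma, adjusted p = 0.636). With Xist minus the Y-linked mean as a covariate, 33 genes were higher and 8 lower, 34 of the 110 genes stayed past the threshold, and all 110 kept their direction. Signals from the 3' and 5' ends of control transcripts were read as a sign of RNA quality. The actin difference of 3' minus 5' was 0.04 in OVE26 and -0.01 in FVB arrays (exact permutation p = 0.317), and that of Gapdh was 2.59 and 2.63 (exact permutation p = 0.556).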

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

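The tests of the 3 patterns weighed here (tubule markers, male-biased genes and clock genes) were chosen after the results had been seen. For more tubule cells of all segments, the rule first used argued against the explanation from all 9 arrays, and the demand that the difference also hold without OVE26 2 was added after both p values had been seen. Arrays far from the rest of their group were looked for in 258 groups of values, of which 19 stood out. About 1 in 20 would by chance, but the 19 cannot be set against that share. The groups include genes chosen after their values were seen, and of these Arntl, Kap, Slco1a1, Cyp4a14, Aqp2, Slc34a1 and Pecam1 stood out. OVE26 2 accounted for 7 of the 19 and FVB 2 for 6. Unless a score is named, values are log2 intensities, and the values of the other arrays of that group follow.

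The list of loop, distal tubule and collecting duct markers was called higher in OVE26 sorts (median 1.00), although sorting on fluorescence should leave such cells out. That call did not hold with an estimated correlation (camera, adjusted p = 0.252). More tubule cells of all segments in the OVE26 sorts remain open: the collecting duct score minus the proximal score was higher by 1.39 (exact permutation p = 0.0317), but by 0.75 without OVE26 2 (exact permutation p = 0.0571). The uneven sex of the groups is argued against as the whole explanation, since the median stayed at 0.88 with the sex covariate (camera at its preset correlation, adjusted p = 5.63e-08). A part played by sex is not excluded. In OVE26 the list's score was 0.29 to 1.43 in arrays with Xist above the Y-linked genes and 0.16 and 0.27 in the others. In FVB it was 0.03 in FVB 2, where Xist was high, and -1.20 to -0.61 in the others. More collecting duct cells may account for the higher list but cannot be told apart from a change inside podocytes. All 13 collecting duct genes measured, a set composed after the data had been seen, had differences above 0, passing or not. In FVB arrays 6 of these 13 were above the 40th percentile. Of the 28 genes of the whole list 26 had differences above 0, so the 13 do not set the collecting duct apart. That principal and intercalated cell scores vary together within groups was not shown at p under 0.05 (Pearson's r = 0.805, exact permutation p = 0.0552, and Spearman's rho = 0.55, exact permutation p = 0.0861). Without OVE26 2 and FVB 4 r was 0.556, and this family held 1 relation. The abundant principal cell gene Aqp2, chosen after its values were seen, was at 6.46 in OVE26 and 5.86 in FVB arrays, and an effect of diabetes on podocytes or on the tubule was not tested.

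The OVE26 2 array stood apart on both tubule scores, at 1.43 for the loop, distal tubule and collecting duct markers (others 0.16 to 0.45) and at -1.69 for the proximal tubule markers (others 0.11 to 0.54). Its macrophage score of -0.28 lay within the FVB range of -0.49 to -0.25, whereas those of the other OVE26 arrays ran from 0.23 to 0.77. In the same array Slc26a4 was at 8.93 (others 7.55 to 7.70), Aqp2 at 7.06 (others 6.22 to 6.44), the phosphate transporter gene Slc34a1 at 5.64 (others 7.70 to 8.36) and the endothelial gene Pecam1 at 8.12 (others 8.49 to 8.57). The fatty acid hydroxylase gene Cyp4a14 was at 2.87 in OVE26 2 (others 7.60 to 9.40). Aqp2 was at 5.93 in FVB 1, where the other 3 FVB arrays shared the value 5.84.

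The score of 20 male-biased kidney genes differed by -1.32 in OVE26 arrays (exact permutation p = 0.103), and 2 of these genes, chosen after their values were seen, had arrays far from the rest: the androgen-regulated Kap was at 5.82 in FVB 2 (others 11.87 to 12.36), and the transporter gene Slco1a1 at 2.50 in FVB 2 (others 8.61 to 9.31) and 6.04 in OVE26 1 (others 2.64 to 3.13). The uneven sex of the groups is a candidate explanation that stays open. Among arrays with Xist above the Y-linked genes, FVB 2 was at -1.36, within the OVE26 range of -1.41 to -0.53, so no fall was seen there. In the 5 arrays with Xist below those genes, where uneven sex cannot act, the male-biased score still differed by -1.64. There 16 of 20 genes were lower in both OVE26 arrays than in all 3 FVB arrays (10% by chance), but 2 against 3 arrays cannot give an exact p under 0.1. Fewer proximal tubule cells are argued against in these 5 arrays only. Other proximal markers differed there by 0.37, from 0.20 to 0.35 in OVE26 and from -0.33 to 0.23 in FVB arrays, which overlap. OVE26 2, outside these arrays, had the lowest score of all 9 arrays for the other proximal markers (-1.59) and for the male-biased genes (-1.41). A lower androgen response in diabetic males was not tested.

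Arntl, the gene of the clock activator BMAL1, was at 6.95 in OVE26 4 (others 3.79 to 4.06) against a mean of 5.78 in FVB arrays, and without OVE26 4 it differed by -1.86 (limma, adjusted p = 0.0180) and its partner Npas2 by -3.33 (adjusted p = 0.0306), which leaves out the 1 OVE26 array that ran against the pattern. The score of activator genes minus output genes differed by -1.69 between groups (exact permutation p = 0.0952). The score of OVE26 4 lay within the FVB range of -0.51 to 1.87, and those of the other OVE26 arrays ran from -1.73 to -0.80. Another time of day at collection may account for this and cannot be told apart from an effect of diabetes on the clock, because no collection times are given in the labels. The uneven sex of the groups was not weighed here and stays open too. The score was -1.59 to -0.51 in arrays with Xist above the Y-linked genes. In those with Xist below it was -1.73 in OVE26 1 and 0.95 to 1.87 in the others. With the sex covariate Arntl differed by -0.77 (limma, adjusted p = 0.560) and Npas2 by -1.92 (adjusted p = 0.362).

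The remaining arrays that stood out are given as values. Mt1 was at 9.57 in FVB 2 (others 7.57 to 7.67), the complement receptor gene C5ar1 at 5.59 in FVB 2 (others 4.31 to 4.42) and Cyp4a14 at 6.73 in FVB 2 (others 2.85 to 3.27). The actin difference of 3' minus 5' signal was -0.14 in FVB 2 (others 0.03). Rpl27 was at 11.61 in FVB 4 (others 11.51 to 11.52), Egln3 at 4.52 in FVB 4 (others 5.08 to 5.13) and Cxcl16 at 6.68 in FVB 3 (others 7.35 to 7.46). Among 10092 probe sets with several gene symbols or none, which the comparison of genes leaves out, 20 passed the threshold by limma, 8 higher and 12 lower in OVE26 arrays.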

How the results depend on the processing

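The tests with distal or macrophage covariates, with OVE26 2 and OVE26 4 left out, on the arrays of either Xist level alone, and without the block over the same arrays were chosen after the results had been seen. All 110 genes kept their direction in the settings that tested them with 1 value per gene. Taken singly, 6 of the 110 had another probe set in the other direction, 0 of them past the threshold by limma. Chance was weighed over 100 splits of the 9 arrays, the real one included. It is made unlikely for the genes higher (1 of 100 splits gave as many as 86, the highest other was 7). The same holds for the genes lower (1 of 100, 24 against 7) and changed at least 2-fold (1 of 100, 78 against 7). It is not excluded, since 1 of 100 is the smallest share these splits can give. For the 22 lists called chance stays open, since 7 of 100 splits called as many. The highest other count of lists, 30, came from the split that grouped FVB 2 with OVE26 1, 3, 4 and 5. Which genes these counts hold is limited by the number of arrays and, for dim genes, by signal near the background.

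With arrays centred on ribosomal protein genes 55 genes were higher and 47 lower, and with arrays centred on their medians 52 were lower. A filter on dim genes gave 128 higher and 38 lower genes from 10916 tested, and an intensity trend with robust variance 128 and 51. Array weights, lowest for OVE26 2 (0.467) and OVE26 4 (0.551), gave 284 higher, 112 lower and 212 changed 2-fold. The endothelial covariate gave 216, 53 and 168, the mesangial covariate 261, 89 and 211, and the sex covariate 33, 8 and 38. The distal covariate gave 0, 0 and 0 by limma (1668 genes at an unadjusted p under 0.05), and the macrophage covariate 0, 1 and 1 (2800 at an unadjusted p under 0.05) with 6 lists called. A linear model without moderation gave 0, 0 and 0 (2518 at an unadjusted p under 0.05). Arrays with Xist below the Y-linked genes gave 7, 3 and 10, from 5 arrays, and those with Xist above gave 0, 0 and 0 by limma with 14 lists, from 4 arrays (938 at an unadjusted p under 0.05), where the lone FVB array is assumed to vary like the OVE26 arrays. At an adjusted p under 0.01, 14 were higher and 1 lower, and under 0.1, 267 and 108. Camera with an estimated correlation called 0 lists (8 at an unadjusted p under 0.05), and fry 15, of which 14 were among the 22. Apart from the standard errors named for the distal and macrophage covariates and the fewer arrays or genes, the cause was not tested.

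Without 1 array, higher genes ranged from 8 to 285, lower genes from 0 to 82 (0 without FVB 3 by limma, with 2155 at an unadjusted p under 0.05), genes changed 2-fold from 8 to 278 and lists from 20 to 25. Genes changed 2-fold numbered 68 without OVE26 1, 96 without OVE26 2, 22 without OVE26 3, 50 without OVE26 4 and 26 without OVE26 5. They numbered 23 without FVB 1, 278 without FVB 2, 8 without FVB 3 and 25 without FVB 4. Of the 110 genes, 8 stayed past the threshold without FVB 3 and 108 without FVB 2. Without both OVE26 2 and OVE26 4 the counts were 62 higher, 17 lower and 64 changed 2-fold, with 24 lists. Of the 110 genes 41 stayed past the threshold there. Of the list calls 2 ended (mesangial and epithelial-mesenchymal transition) and 4 were gained.

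With replicate number as a block, over the 8 arrays numbered 1 to 4 in both groups, 19 genes were higher, 0 lower (limma, 2339 at an unadjusted p under 0.05) and 19 changed 2-fold, with 18 lists. The same arrays without the block gave 27, 3 and 26, with 20 lists. The numbers do not pair the samples: deviations of same-numbered arrays correlated at 0.129, 0.0421, -0.212 and 0.00762, and 0 of 4 numbers had arrays that correlated best with each other.

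Under the macrophage covariate the camera direction turned for 5 lists. Their medians were -0.0556 for interferon and -0.0519 for complement, which changed sign, and 0.0084 for inflammatory, 0.0373 for immediate early and 0.0218 for NADPH oxidase genes, which stayed above 0. Of the 21 list calls tested with each of these covariates 17 ended with the macrophage covariate and 7 with the distal covariate, and of all 22 calls 3 ended with the sex covariate. In the arrays with Xist below the Y-linked genes (2 OVE26 and 3 FVB) 4 ended (matrix, NADPH oxidase, hypoxia and epithelial-mesenchymal transition) and 3 were gained (glucose transport, clock and glomerular endothelial, the last lower). The calls lost and gained in arrays with Xist above are not read, since they compare 3 OVE26 arrays with 1 FVB array. The proximal tubule list, not called at -0.08, was called higher at 0.97 with the distal covariate, 0.39 without OVE26 2 and 0.49 without OVE26 2 and OVE26 4, and lower at -1.51 with the macrophage covariate. Without 1 array its median ranged from -0.25 to 0.39. The cause was not tested. Over all settings single named genes held their side of the threshold in 2780 comparisons, lost it in 453 and gained it in 123. Lists held it in 1315, lost it in 106 (5 with the direction turned) and gained it in 39 (3 with the direction turned), where a change of sign with neither side past the threshold counts as held.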

Other observations

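The comparisons of nephron segment scores, male-biased genes and clock genes in this part were chosen after the results had been seen, and so were the genes named. The principal cell score was higher by 1.41 and the intercalated cell score by 1.65 in OVE26 arrays (each exact permutation p = 0.00794, the smallest possible; adjusted p = 0.0374 over 33 measures), and the distal convoluted tubule score differed by 1.13 (exact permutation p = 0.0794) and the thick ascending limb score by 0.68 (exact permutation p = 0.198). The differences between segments were not themselves tested. Transcripts of the thick ascending limb were bright in both groups: Umod, the uromodulin gene, was at 11.16 in OVE26 and 10.94 in FVB arrays, Egf at 10.39 and 10.56, and the sodium transporter gene Slc12a1 at 10.14 and 9.59. Of proximal tubule genes the endocytic receptor gene Lrp2 differed by -0.44 (limma, adjusted p = 0.785) and Slc34a1 by -0.09 (adjusted p = 0.962), or by 0.01 (adjusted p = 0.993) and 0.40 (adjusted p = 0.324) without OVE26 2.

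Within the macrophage list, members did not move alike. The mannose receptor gene Mrc1 differed by -1.35 (limma, adjusted p = 0.191) and was the 1 member lower when adjusted over the list alone, while Ctss, C1qb and Tyrobp lay above 0. The neutrophil score was higher by 0.42 and the B and plasma cell score by 0.20 (each exact permutation p = 0.00794, adjusted p = 0.0374), and neither list was called by camera. Without Lcn2 the neutrophil score differed by 0.06 (exact permutation p = 0.389), and without Blnk and Sdc1 the B and plasma cell score by 0.00 (exact permutation p = 1), so these members carried the differences. Of clock genes, Npas2, whose protein pairs with BMAL1, differed by -2.49 (limma, adjusted p = 0.225) and Arntl by -1.25 (adjusted p = 0.375). Per2 differed by 1.17 (limma, adjusted p = 0.220), or 1.61 without FVB 2 (adjusted p = 0.0335), and Dbp by 0.75 (adjusted p = 0.527). Of immediate early genes Egr1 differed by 1.21 (adjusted p = 0.200) and Fos by 0.53 (adjusted p = 0.286), and the immediate early score differed by 0.48 (exact permutation p = 0.0714). Of vascular and mesangial genes, Kdr, a VEGF receptor of endothelium, differed by -0.46 (adjusted p = 0.490) and Pdgfrb by -0.18 (adjusted p = 0.834).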
